A study of Gallus gallus with 20 samples.

How the data were processed

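Total RNA was measured in pieces of mid-ileum, the last part of the small intestine, from broiler chickens aged 35 days. Per the labels' protocols, tissue was kept in RNAlater, disrupted by bead beating and purified on columns, ribosomal RNA was depleted and strand-specific Illumina libraries were made. The labels place 5 birds in a control group and 5 in a group named for avilamycin, and they give 2 technical libraries for each bird, 20 in all. The dose and the duration of feeding are not given in the sources used here. The series' design text describes 2 sequencing runs, but it assigns them by sample numbers that no label carries, so run was not used to group libraries.

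The authors deposited a table of raw read counts for 24356 Ensembl gene IDs in the 20 libraries. The counts are whole numbers with a different total in every library, and every line carries a gene ID. The submitters' processing notes name Trimmomatic 0.36, STAR, SAMtools 1.7, HTSeq 0.6.1 and DESeq2, with no role or order. They also name the genome build galGal5, whereas the name of the deposited count table gives GRCg6a, so no coordinates are printed. Whether the counting used the strand of the reads is not given in the sources used here, so values of overlapping genes, antisense genes and members of gene families are uncertain. A second deposited file, named as a list of differentially expressed genes, proved byte for byte identical to the count table and was not used.

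The deposited table gives gene IDs without symbols. The reference gene table used here (assembly GRCg7b) lists 25635 genes and gives an Ensembl ID for 0 of them, so 0 IDs were matched to a symbol. For this reason the 36 gene lists fixed before the data were examined, markers of cell types among them, were not tested. The rule for named genes, fixed at the same time, asked for the largest changes past the threshold, for list members, and for the 10 genes with the smallest p where fewer than 10 passed. With no symbols, the 2 gene IDs with the smallest p in each direction are printed and the 10 genes are summarised.

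The bird was taken as the replicate, and the counts of its 2 libraries were summed. Genes were kept by edgeR's filterByExpr, which left 15516, and library sizes were scaled by TMM. Avilamycin was compared with control by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05, with group as the only term. Standard errors of log2 fold changes were derived from the F statistic. Levels are given as CPM (counts scaled to a common library total) on the TMM scale, except for a block of 19 genes, whose CPM are of total counts. Separation of the groups was measured by the pseudo-F of squared distances in log2 CPM (prior count 2) and tested exactly over all 252 assignments of 10 birds to 5 and 5. The distance of each bird from its group mean was compared in the same way. The 2 libraries of a bird were compared by Pearson correlation of log2 CPM and by a chi-square per gene over genes with at least 20 counts in the pair.

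For the gene test, alternatives fixed before the data were examined were DESeq2 size factors, no filter, a filter at 10 CPM in 5 birds, each bird left out, each technical library number alone, the bird number or the technical number as a block, DESeq2 1.42.0, limma 3.58.1 voom, and all 20 libraries as separate samples. For the separation and the distances they were DESeq2 size factors, the filter at 10 CPM, prior counts of 5 and 0.5 and the 500 genes with the largest variance, and for the correlation of libraries Spearman's method and the filter at 10 CPM. A covariate for the block of 19 genes (their mean log2 CPM in each bird), the birds without the block, omission of genes that follow it, assignments that keep the share of the birds with it, the omission of single birds from the separation, and other forms of the quasi-likelihood fit were chosen after seeing the data.

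Library totals ran from 14079936 to 26708365 counts and bird totals from 31130907 to 45371754. The tests were tested on counts simulated from the means, dispersions and library sizes of this comparison, with 200 of 15516 genes changed. Of these, 67 were changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold. Recovery depends on this mix, since large changes ease the adjusted threshold. The edgeR test recovered 38.8% of genes changed by 1.5-fold, 70.1% of those changed by 2-fold and 92.4% of those changed by 4-fold, with 11 false calls among 145. DESeq2 recovered 52.2%, 80.6% and 95.5%, with 43 false calls among 195.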

Results

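Ileal transcriptomes were compared between 5 control broilers and 5 broilers of the avilamycin group at 35 days of age. Avilamycin is an oligosaccharide antibiotic that acts on Gram-positive bacteria and has been fed to poultry as a growth promoter. The question was how such a growth promoter relates to gene expression in the intestine of the host. Control birds had 37579995 ± 4655901 counts (SD, n = 5) and avilamycin birds 41922735 ± 3288545 (SD, n = 5), a difference within the spread between birds (exact permutation test, two-sided, p = 0.127). Each library detected between 17733 and 18445 genes. The most abundant gene took 12.2% to 15.8% of the counts of a library, and the 3 most abundant together took 20.3% to 23.7%.

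The libraries grouped by bird. For all 20 libraries, the closest match in log2 CPM was the other library of the same bird. Correlations across genes between these partners were 0.989 to 0.992, whereas the highest correlation with a library of another bird was 0.984. Genes are not independent replicates, so these correlations describe the libraries only. The 2 libraries of a bird nevertheless differed by more than sampling noise, with a mean chi-square per gene between 2.30 in bird D5 and 7.13 in bird D7, where 1 is the value for pure sampling. The median correlation between libraries of different birds was 0.977 within a group and 0.976 between groups.

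Ileal expression as a whole separated the groups. On the first principal component, which held 22.9% of the variance between birds, all avilamycin birds (8.58 to 25.4) lay above all control birds (-50.3 to 5.87). The group accounted for 17.3% of the squared distance between birds. A random assignment also accounts for some of it, so 17.3% is not the share due to the group. The pseudo-F was 1.67. No other assignment of the 10 birds to 5 and 5 gave as large a value, so that the exact permutation p of 0.00794 (one-sided) is the smallest this design allows. A block of 19 genes was on in 3 of 5 control birds and 1 of 5 avilamycin birds. Among the 60 assignments that keep this share of the 4 birds in each group, no other had as large a pseudo-F (exact permutation test, one-sided, p = 0.0167, the smallest possible). With the level of the block regressed out of every gene, which also removes group differences that go with it, the pseudo-F was 1.46 (exact permutation test, one-sided, p = 0.0714).

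**Figure D1:**
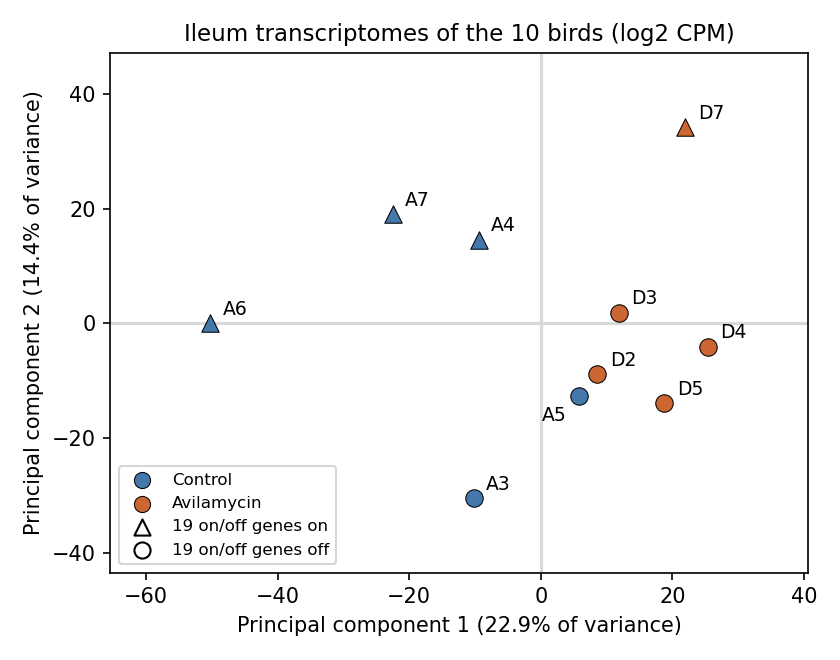
Principal components 1 and 2 of log2 CPM over 15516 genes for the 10 birds, in arbitrary units with the percent of variance on each axis. Blue points are control birds, orange points avilamycin birds and triangles birds in which the 19 genes were on. All 5 avilamycin birds lie at 8.58 or above on component 1 and all 5 control birds at 5.87 or below.

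The birds of both groups lay at similar distances from their group mean. In units of log2 CPM over all genes, the distance was 42.9 ± 2.1 in control birds (SD, n = 5) and 41.7 ± 2.8 in avilamycin birds (SD, n = 5). The difference of -1.13 was within the spread between birds (exact permutation test, two-sided, p = 0.468).

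No single gene passed the threshold between avilamycin and control birds. Of 15516 genes, 0 had an adjusted p under 0.05 and 2 had an adjusted p under 0.1 in edgeR's quasi-likelihood test. Genes at an unadjusted p under 0.05 numbered 1721, or 11.1%, where chance gives 776. Of these, 828 had higher and 893 lower values in avilamycin birds, with a median absolute log2 fold change of 0.38. Other fits gave different numbers of called genes. Limma voom on the same genes and summed counts called 0, with 1747 at an unadjusted p under 0.05. DESeq2, with its own filter, called 194 genes, 97 higher and 97 lower, and gave 2084 of 21458 genes (9.71%) an unadjusted p under 0.05. A voom fit of single libraries with the technical number as a replicate block and the bird as a random effect called 243 genes. It used a single correlation of 0.635 between the libraries of a bird for all genes. For genes whose libraries agree more closely, this counts technical libraries in part as replicates.

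**Figure D2:**
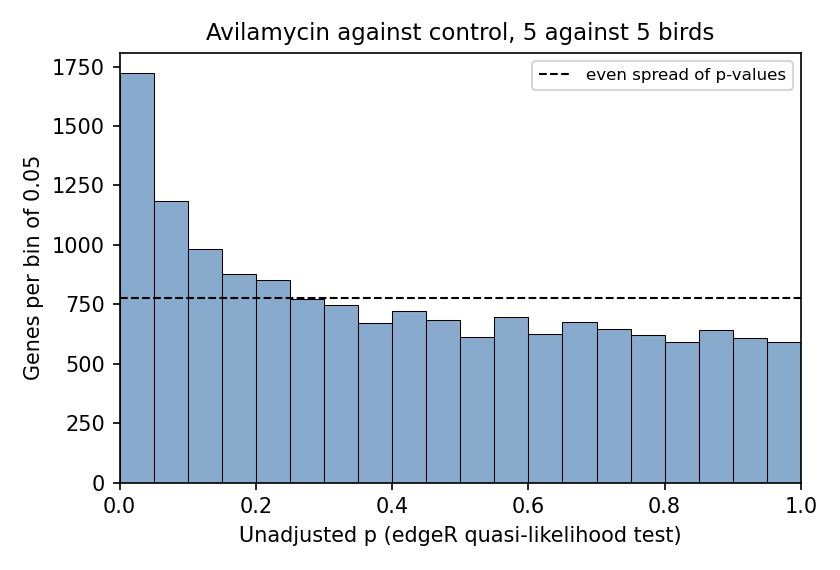
Histogram of unadjusted p-values of edgeR's quasi-likelihood test for avilamycin against control, as genes per bin of 0.05 over 15516 genes. The dashed line marks the 776 genes per bin of an even spread, and the first bin holds 1721 genes.

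Genes at an unadjusted p under 0.05 were found at every level of abundance. They made up 8.97% of the 5172 genes with the lowest mean level (up to 6.31 CPM), 11.3% of the 5172 in the middle and 13.0% of the 5172 with the highest (from 34.0 CPM). Their median absolute log2 fold change was 0.74, 0.34 and 0.27 in these classes, and the smallest was 0.23, 0.12 and 0.11. The medians cover only genes past this p, so they do not show that scarce genes differed more. Among the most abundant genes, 362 of those at this p had higher values in avilamycin birds and 310 lower. In the middle class 251 were higher and 334 lower, and in the lowest class 215 were higher and 249 lower. The groups did not overlap for 290 genes, with all 5 avilamycin birds above all 5 control birds for 161 genes and below them for 129. This was 1.87% of the genes tested, where chance gives 0.794%, or 123 genes.

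The 10 genes with the smallest p comprised 8 with higher and 2 with lower values in avilamycin birds, with absolute log2 fold changes from 0.47 to 2.60. For all 10 the groups did not overlap, which their choice by p favours, and the largest adjusted p was 0.165 (edgeR). ENSGALG00000053914 had the smallest p of all genes. It was at 0.574 ± 0.290 CPM in control birds (SD, n = 5), from 14 to 34 counts per bird, and at 3.45 ± 1.10 CPM in avilamycin birds (SD, n = 5), from 93 to 212 counts. Its log2 fold change was 2.60 ± 0.33 (SE; edgeR adjusted p = 0.0793). ENSGALG00000001035 was similarly scarce, at 0.348 ± 0.144 CPM in control and 1.93 ± 0.705 CPM in avilamycin birds (SD, n = 5 each). Its log2 fold change was 2.46 ± 0.36 (SE; edgeR adjusted p = 0.122).

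The 2 genes with lower values in avilamycin birds were more abundant. ENSGALG00000031164 was at 21.4 ± 7.50 CPM in control birds, from 465 to 1044 counts per bird, and at 4.74 ± 1.72 CPM in avilamycin birds, from 125 to 298 counts (SD, n = 5 each). Its log2 fold change was -2.17 ± 0.29 (SE; edgeR adjusted p = 0.0793). ENSGALG00000002722 was at 25.8 ± 11.6 CPM in control and 6.89 ± 1.97 CPM in avilamycin birds (SD, n = 5 each), a log2 fold change of -1.91 ± 0.32 (SE; edgeR adjusted p = 0.150).

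**Figure D3:**
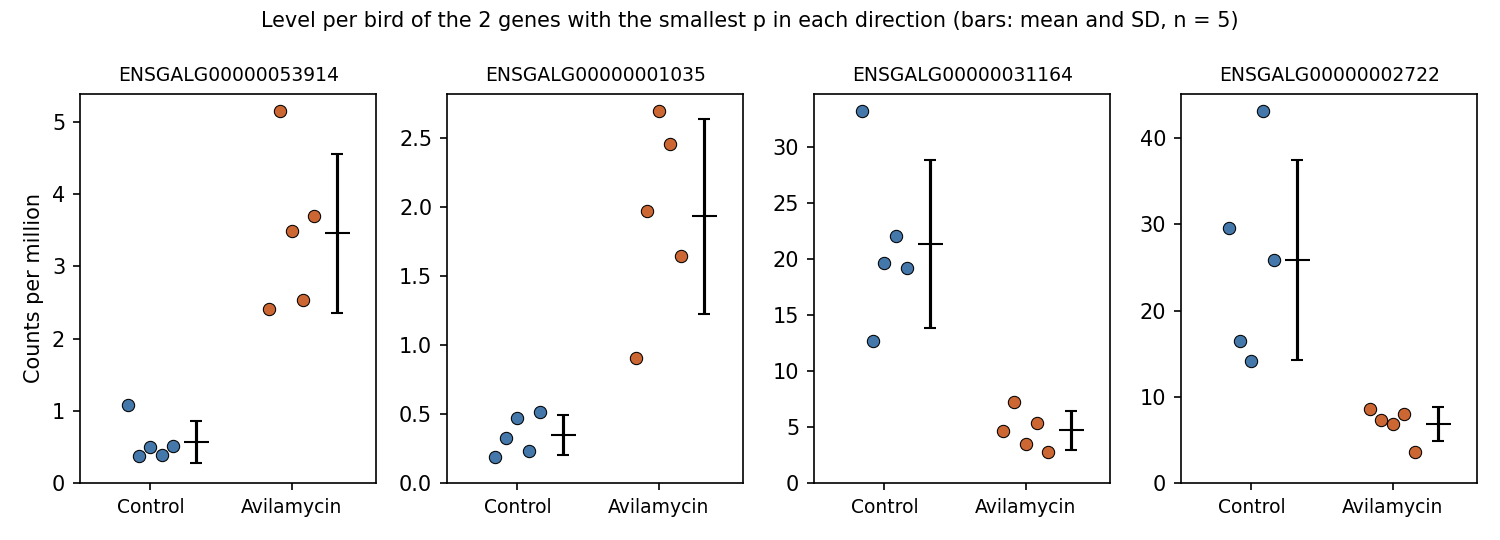
Level in CPM (TMM scale, linear axes from 0) of the 2 genes with the smallest p in each direction. Each point is a bird, blue for control and orange for avilamycin, and bars give mean and SD (n = 5). The values of the groups do not overlap for any of the 4 genes, which their choice by p favours.

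The adjusted p of these 4 genes differed between fits. DESeq2 gave adjusted p of 4.46e-12 for ENSGALG00000053914, 1.02e-07 for ENSGALG00000001035, 2.46e-11 for ENSGALG00000031164 and 6.27e-07 for ENSGALG00000002722. The highest adjusted p over all alternatives, in the same order, were 0.722, 0.800, 0.237 and 0.515, all from an edgeR fit of the 6 birds without the block of 19 genes. ENSGALG00000053914 passed edgeR's threshold without control bird A3 or without avilamycin bird D2, and ENSGALG00000001035 without D2. With technical number 2 alone, ENSGALG00000053914 and ENSGALG00000031164 passed it (edgeR adjusted p = 0.0436 for both).

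A block of 19 genes divided the birds across the groups. It was picked by its pattern. In all, 26 genes were above 1 CPM in some birds and under 0.1 CPM in all others, and 19 of them shared 1 pattern. The next commonest pattern held 1 gene. By this choice each of the 19 was above 1 CPM in control birds A4, A6 and A7 and avilamycin bird D7, and under 0.1 CPM in the other 6 birds. Their summed level was 155 to 170 CPM in the 4 birds and 0.193 to 0.659 CPM in the other 6. The filter on low counts kept none of the 19, so they are not among the genes tested above. With their mean log2 CPM as a covariate, 1444 genes had an unadjusted p under 0.05, 813 higher and 631 lower in avilamycin birds, and 1 gene passed the threshold of edgeR's quasi-likelihood test. This was ENSGALG00000031164, with a log2 fold change of -2.43 (adjusted p = 0.0289). The log2 fold change was then 2.50 for ENSGALG00000053914, 2.40 for ENSGALG00000001035 and -1.98 for ENSGALG00000002722.

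Comparisons among birds alike in the block had few birds. Among the 6 birds without the 19 genes, 2 control and 4 avilamycin, the pseudo-F was 1.07 (exact permutation test, one-sided, p = 0.333), where 15 assignments cannot reach 0.05. In these 6 birds 777 of 15995 genes, or 4.86%, had an unadjusted p under 0.05 in edgeR's test, 496 higher and 281 lower. This is no more than the 5% that chance gives. No excess over chance was thus seen, but so small a design does not exclude one. In the same test 0 genes passed the threshold. The counts are not comparable with those of 10 birds. The 4 birds with the block include 1 avilamycin bird and were not compared by group.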

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

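No test in this part was chosen after the result was seen, but 8 of the 18 sets of 5 birds tested are levels of the 4 named genes, which were picked by their p. About 1 in 20 sets would hold a value that stands apart by chance, and 1 of the 18 did. Control bird A3 had 1.08 CPM of ENSGALG00000053914, and the next highest control bird had 0.514 CPM, a gap of 0.810 of the range of the control birds.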

How the results depend on the processing

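The fits that use the block of 19 genes, the other forms of the quasi-likelihood fit, the unblocked fit of 8 birds, the assignments that keep the share of the 4 birds and the omission of single birds from the pseudo-F were chosen after the results were seen. The 4 named genes kept their direction under every alternative that gave a value. The count of 0 called genes held with DESeq2 size factors, no filter, the stricter filter, voom, technical number 1 alone, both other forms of the quasi-likelihood fit and the omission of genes that follow the block. Without 1 bird it ranged from 0 to 3 (2 without control A3, 3 without avilamycin D2, 1 without avilamycin D4). It was 2 with technical number 2 alone, 1 with the covariate and 194 in DESeq2. DESeq2 with the covariate gave 124 (75 higher and 49 lower, 85 shared with the 194). Voom of single libraries, with the technical number as a replicate block and a single correlation for all genes, gave 243. Treating 20 libraries as separate samples, which counts technical libraries as replicates, gave 1153 calls and 3397 genes at an unadjusted p under 0.05. Among the fits without 1 bird, genes at such a p ranged from 1189 (7.59%, without control A6) to 2045 (13.0%, without control A5). In the 6 birds without the block that number was 777 (4.86%, no more than the 5% that chance gives) and the pseudo-F 1.07, in a smaller design. With the covariate regressed out, the pseudo-F was 1.46. Without 1 bird it ranged from 1.30 to 1.85, and it stayed past the threshold with every filter, prior count, scaling and gene set tried. The spread kept its direction and stayed within chance, and all libraries matched their partner in each form tried. Bird numbers 3, 4, 5 and 7 occur in both groups, but same-numbered birds did not deviate together (correlations of -0.034 to 0.083). As a replicate block the number gave 0 calls and 1351 genes at an unadjusted p under 0.05 (718 higher and 633 lower), against 1519 in the same birds unblocked. The causes of these differences were not tested. Without gene symbols or chromosomes, the gene list tests and the alternatives for the sex chromosomes and smooth muscle were not run. At these depths, with 5 birds per group, the simulated edgeR test recovered 38.8% of 1.5-fold and 70.1% of 2-fold changes. The simulated counts held no structure shared by birds, and 66 of the 200 changed genes were changed by 4-fold, which eases the adjusted threshold. Recovery in the real data may therefore be lower.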

Other observations

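The edgeR and DESeq2 tests of the groups were planned and the bounds for thinning to equal depth were set before its result was seen, while the splits of the birds and the tests of the block of 19 genes, of its reads in birds without it and of the library differences were chosen after the results were seen.

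Genes at an unadjusted p under 0.05 numbered 1721, against 776 by chance. Chance is argued against for this count at a bound of 5%. Of 100 drawn splits of the 10 birds, 2 gave as many, the real one included. It is not excluded, since only 100 of the 126 possible splits were drawn, after the result was seen. The highest other split, which exchanges control bird A5 for avilamycin bird D2, gave 1854. Unequal depth is argued against, since 1686 genes had such a p with every bird thinned to 31130907 counts. The uneven share of the 4 birds with the block of 19 genes stays open. Of 49 splits that part the 4 birds alike, 2 gave 1721 or more, the real one included. With the covariate the count was 1444 (above a limit of 1164), and 3 of the 49 splits gave as many (highest other 1601). Without the genes that follow the block the count was 1722 of 15214. That omission cannot decide, since it took out only 302 genes, too few to bring 1721 down to the limit. Avilamycin, and differences between the groups that the labels do not record, such as pens, stay open and untested.

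Chance cannot be excluded for the calls of DESeq2. Of the 100 splits, 9 gave 194 calls or more, the real one included, and the highest other split gave 362. In 5 of the 9 all 4 birds with the block were in 1 group, which points to a structure of the birds. The remaining splits exchange avilamycin bird D2 for control bird A7 (200 calls), A5 (362) or A3 (244). They otherwise keep the real groups, so a difference between the groups could raise their calls too. Of the 49 splits that part the 4 birds alike 3 gave as many, the real one included, and the others were exchanges of this kind. Of the 194 genes edgeR tested 186, all with the same sign and an unadjusted p of at most 0.00668. In edgeR, 5 other splits gave any gene past the threshold, at most 2.

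The block of 19 genes was on in 4 birds and off in 6. The division reached beyond the 19 genes. Between the 4 birds and the other 6, 303 further genes differed (edgeR, adjusted p under 0.05, group in the model), against at most 2 for 30 random sets of 4 birds. The 4 birds were themselves picked from these data, by the 19 genes, and the random sets were not. The count of 303 leaves a change at a single locus open. Such a change may alter other genes, and no gene was placed on a chromosome. The mean log2 CPM of the block was followed by 302 genes, of which 95.4% were lower where the block was on, by a median of 1.64-fold. A candidate explanation is the sex of the birds, since hens carry a W chromosome that cocks lack and a single Z, whose dosage is only partly compensated. This remains a hypothesis, because the labels give no sex and no chromosomes were assigned to the genes here.

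Differences between the second and the first library were shared by birds A4, A6, A7, D2, D3 and D7, 3 of each group, with pairwise correlations across 7795 genes of 0.258 to 0.539, whereas all other pairs of birds lay between -0.214 and 0.105. These 6 were picked as the birds whose differences correlated above 0.2 with at least 1 other bird. By this rule no other pair could lie above 0.2. Unequal depth is argued against, since the median correlation among the 6 birds was 0.338 with both libraries of each bird thinned to the same total. A candidate explanation is that the 2 libraries of these birds were sequenced in different runs, with some reads passing between libraries of a run, but the tests leave this open, as they do library preparation on different days. In D2 and D3, which lack the block, the first libraries held 2.06 times the block CPM of the second (32 against 12 counts, exact binomial test, two-sided, p = 0.0328), but this p covers counting error only, and 80 of 729 other genes within 10 counts of that total were as unequal between these libraries. The other 4 birds without the block held 15 and 22 counts (ratio 0.765, exact binomial test, two-sided, p = 0.511).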
